A study of Homo sapiens with 2 samples.

How the data were processed

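The series holds 2 chromatin immunoprecipitation sequencing (ChIP-seq) libraries from U2OS, an established human osteosarcoma cell line. One library was made with an antibody to histone H4 monomethylated at lysine 20 (H4K20me1) and the other with an antibody to the trimethylated form (H4K20me3). Per the labels' protocols, about 10000000 cells went into each reaction, chromatin was sheared by sonication to fragments of 200 to 400 bp on average, and libraries were sequenced as single-end reads of 50 bp. There was 1 library per mark. No replicate, input control or untreated sample was analysed here.

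The deposited files are peak lists, 1 per library, with a chromosome, a start, an end and a peak name on each line. The submitters' processing notes name Bowtie, a short-read aligner, MACS2, a peak caller, and the genome build hg19. Versions, settings, the use of an input control and the handling of reads that map to several places are not given in the sources used here. The lists carry no read count, height, fold enrichment or q-value per peak, so peaks could not be ranked by strength and the sequencing depth behind them is unknown. Each list was called on a single library, and the number of peaks called moves with depth and antibody efficiency. The absolute numbers of the 2 lists are therefore not comparable as amounts of the modification. In both lists the smallest gap between neighbouring peaks was 801 bp and the narrowest peak was 200 bp, so smaller gaps and narrower sites were not resolved.

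Peaks on chromosomes 1 to 22 and X were used. This kept 44738 of 44741 H4K20me1 peaks and 7844 of 7853 H4K20me3 peaks. Peak names are numbered up to 44780 and 7932. The 39 and 79 absent numbers all fall between the last peak of one chromosome and the first of the next, and the sequences they belonged to were not analysed here. Starts were read as counted from 0, after the file type, and all positions are printed counted from 1 on hg19. Chromosome lengths of hg19 were not used. The span of a chromosome is the distance from the first to the last peak of either list, 2937 Mb in all, and percentages of a chromosome refer to that span.

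Because each mark had 1 library, no test between conditions could be made and no p-value is given. Overlaps were set beside random placements of the H4K20me3 peaks. All peaks of a chromosome were moved together along its span by a random distance, wrapping at the end, which keeps peak widths and spacing (a circular shift). The median and central 95% range of 1000 such placements are given, 100 for correlations over windows. These ranges describe how peaks lie relative to each other in these libraries and leave out the spread between cultures. Shares of peaks carry a 95% exact (Clopper-Pearson) binomial interval, which covers counting error only and treats neighbouring peaks as independent. Chosen after the values were seen, shifts were repeated for distances with long peak-free intervals closed up, so that no peak's start fell in one, and the 10 largest domains with 250 kb on either side were each placed 1000 times at random on their chromosome. A peak touched another when at least 1 bp was shared. Domains were made by joining peaks of one mark at most 10 kb apart, and their number was compared with 100 independent random placements of the same peaks. The overlap procedure was tested on simulated lists of 7844 peaks placed against the real H4K20me1 list. Simulated peaks were placed independently of each other, so the test does not cover lists as clustered as the real H4K20me3 list. With no avoidance built in, the ratio of touching peaks to placed peaks averaged 0.995 ± 0.031 (SD, 20 draws). With 50% of touching places removed (an expected ratio of 0.5) it averaged 0.499 ± 0.025, and 20 of 20 draws fell below the range of placements. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

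The main comparisons, some of the alternatives and the rule for named items were fixed before the data were examined. The rule took the 10 domains of each mark with the most covered bases, to be named in order of rank. The distance classes, the chromosome ends and the shares beside peak-free intervals were not among the comparisons fixed in advance. The 1 Mb windows, the joined stretches, the largest overlaps and the peak-free intervals that are also named were chosen after their values were seen. Planned annotation of peaks to genes, the 18 planned gene lists, base composition, and the alternatives that need a peak score could not be run, because the gene table available was of another build (GRCh38) and the lists hold no scores. The genes that lie under the peaks are thus not named here.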

Results

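To map where 2 methylation states of histone H4 lysine 20 lie in one cell type, H4K20me1 and H4K20me3 were profiled by ChIP-seq in U2OS osteosarcoma cells. H4K20me1 is the monomethyl form, made by the enzyme SETD8 (also called KMT5A). H4K20me3 is the trimethyl form, made by the SUV420H enzymes from lower states and known as a mark of heterochromatin. The study's title places both marks in the timing of DNA replication. Each mark was represented by 1 library and 1 list of peaks on hg19, so values describe these 2 libraries and have no replicate error. Read depth was unknown.

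The H4K20me1 list was larger and its peaks were broader. It held 44738 peaks that covered 122.0 Mb, or 4.16% of the mapped span, whereas H4K20me3 held 7844 peaks that covered 7.49 Mb, or 0.255%. The lists thus differed 5.70-fold in peak number and 16.3-fold in covered length. The median H4K20me1 peak was 1115 bp wide with an interquartile range of 545 to 2621 bp. For H4K20me3 the median was 703 bp. Peaks of 5 kb or more made up 13.1% of the H4K20me1 list (95% interval 12.8 to 13.4%) and 0.625% of the H4K20me3 list (0.463 to 0.825%). The widest single peak reached 111939 bp for H4K20me1 and 10942 bp for H4K20me3. Neighbouring H4K20me1 peaks lay a median of 2475 bp apart and H4K20me3 peaks 84967 bp apart. The threshold of peak calling and the depth of each library could change these numbers, and neither is known.

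The marks were spread differently over the chromosomes. H4K20me1 was densest on chromosome 22, where its peaks covered 18.0% of the span, followed by chromosome 17 with 10.6%, chromosome 19 with 9.83% and chromosome 16 with 7.25%. The median over the 22 autosomes was 4.22%. H4K20me3 was densest on chromosome 19, which is rich in genes for KRAB zinc finger proteins, a family of DNA-binding repressors. Its peaks covered 1.29% of chromosome 19, 5.51 times the autosomal median of 0.234%. Chromosomes 22, 7 and 10 came next, with 0.486%, 0.471% and 0.419%. Chromosome 19 carried 10.1% of all H4K20me3 bases and 4.74% of H4K20me1 bases. By number it held 631 H4K20me3 peaks, 8.04% of the list (95% interval 7.45 to 8.67%), against 3.89% of the H4K20me1 list (3.71 to 4.07%).

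Relative to H4K20me1, the H4K20me3 share was highest on chromosome 19 (2.14 times the H4K20me1 share), chromosome 18 (1.81), chromosome 4 (1.77) and chromosome 7 (1.73). It was lowest on chromosome 17 (0.344), chromosome 22 (0.441) and chromosome 16 (0.478). The H4K20me3 share exceeded the H4K20me1 share on 10 of the 23 chromosomes. Both marks were sparsest on the X chromosome, where H4K20me1 covered 0.817% and H4K20me3 0.0433% of the span. The autosomal medians were 5.17 and 5.41 times higher, and the lowest autosome for H4K20me1 was chromosome 4 with 1.63%. Over the 23 chromosomes the covered percentages of the marks had a Spearman correlation of 0.621. Chromosomes are not replicates, and no account was taken of the copy number of each in this line.

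**Figure D1:**
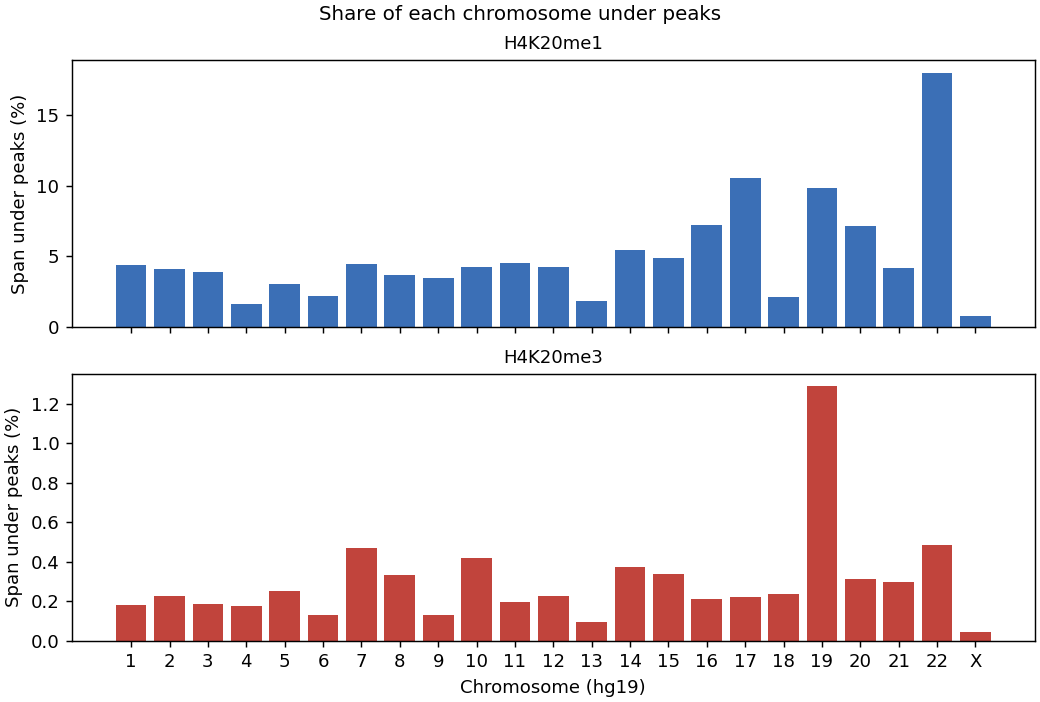
Bars give the percentage of each chromosome's span (hg19) that lay under peaks of H4K20me1 (upper panel) and H4K20me3 (lower panel), 1 library each, on separate linear axes. H4K20me1 peaked at 18.0% on chromosome 22 and H4K20me3 at 1.29% on chromosome 19, and both were lowest on X.

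The first comparison of the design asks whether the marks occupied the same places. They rarely did. Of the 7844 H4K20me3 peaks, 180 touched an H4K20me1 peak, which is 2.29% (95% interval 1.97 to 2.65%), and 75 lay wholly inside one. Under circular shifts a median of 502 peaks touched H4K20me1, with a central 95% range of 427 to 580. In bases, 156.7 kb or 2.09% of H4K20me3 lay under H4K20me1, against 5.08% under the shifts (range 4.08 to 6.14%), a ratio of 0.412. None of the 1000 placements gave as little overlap, and the lowest of them gave 3.68%. From the other side, 178 of the 44738 H4K20me1 peaks (0.398%) touched H4K20me3.

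The shortfall was found on most chromosomes. Fewer H4K20me3 peaks touched H4K20me1 than the median placement on 20 of 23 chromosomes, and the number lay below the range of placements on 16. On chromosome 19, 14 peaks touched against 81 placed (range 37 to 124). On chromosome 10 there were 4 against 31 (range 16 to 53), and on chromosome 11 there was 1 against 16 (range 8 to 27). Chromosomes 13, 18 and X did not have fewer than placed, with 5, 5 and 1 touching peaks and ranges that contained those counts. On chromosomes 7 and 8 the numbers, 26 and 17, also lay inside the ranges of 17 to 91 and 11.98 to 47. In bases, the overlap was below the median placement on 18 chromosomes and below the range on 11. It was above the median on chromosomes 7, 8, 13, 18 and X, inside the range on each. Chromosome 7 shared 29.3 kb against 28.4 kb placed (range 9.65 to 76.6 kb) and chromosome 8 shared 23.1 kb against 16.2 kb (range 6.61 to 41.3 kb), together 33.4% of all shared bases.

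The shared bases were concentrated in a few sites. The 10 H4K20me3 peaks with the most shared bases held 46.2 kb, or 29.4% of the total. The first was the peak at positions 6736224 to 6745070 of chromosome 7, with all of its 8847 bp under H4K20me1. The second, at 146064909 to 146074591 of chromosome 8, shared 7625 bp, which was 78.8% of the peak. The third was again on chromosome 7, at 6689859 to 6695960, with 6102 bp and the whole peak shared.

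H4K20me3 peaks were also scarcer than placed just beside H4K20me1. Peaks less than 1 kb away, without touching, made up 1.39% of the list against 2.21% under the shifts (range 1.81 to 2.61%). At 1 to 10 kb the share was 6.34% against 7.68% (range 6.77 to 8.54%). The order was the opposite at 100 to 500 kb, with 38.9% of peaks against 30.7% placed (range 28.5 to 32.8%). These differences stayed when placements were kept out of peak-free intervals of 3 Mb or more, and of 1 Mb or more, where 33.3% were placed at 100 to 500 kb (range 31.4 to 35.5%). At 1 Mb or more from H4K20me1 the order depended on those intervals. The share was 8.49% against 14.7% over the whole span (range 12.4 to 17.4%), but 6.15% were placed with intervals of 1 Mb or more kept out (range 4.77 to 8.38%). The order also turned at 10 to 50 kb, where 17.03% of peaks lay. This was above the range over the whole span (13.65 to 16.43%) and below that with those intervals kept out (17.26 to 20.0%). The same step moved the share at 50 to 100 kb from above its range to inside it, and that at 500 kb to 1 Mb from inside to above. The median distance of 151.8 kb was inside the range of the placements, 138.9 to 193.0 kb.

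**Figure D2:**
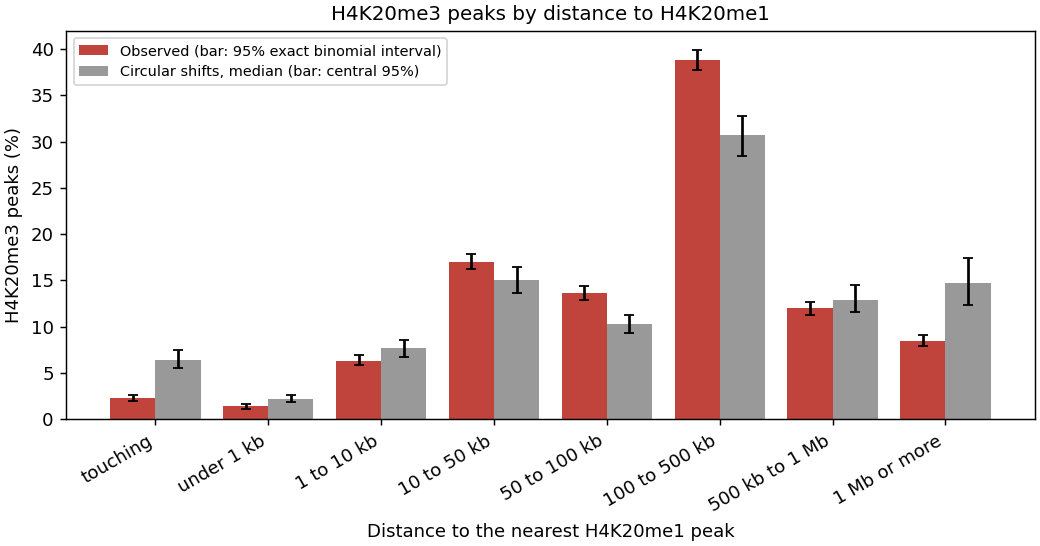
Percentage of the 7844 H4K20me3 peaks (red, bars 95% exact binomial intervals) in each class of distance to the nearest H4K20me1 peak, beside 1000 circular shifts (grey, median with central 95% range). Observed peaks were fewer at touching distance (2.29% against 6.41%) and more frequent at 100 to 500 kb (38.9% against 30.7%).

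The relation between the marks depended on the size of the window. In 100 kb windows that held at least 1 peak of either mark (11558 windows), the Spearman correlation of covered bases was -0.603. Leaving out empty windows forces a negative value, and the shifts gave -0.571 with a range of -0.590 to -0.556, so the observed value lay just below the range. With empty windows included, the correlation was 0.003 at 100 kb (range of shifts 0.010 to 0.034) and -0.017 at 10 kb (range 0.002 to 0.013). In larger windows the order turned. The correlation was 0.216 at 1 Mb (range 0.044 to 0.129) and 0.429 at 5 Mb (range 0.109 to 0.245), above placement in both cases. The shifts moved H4K20me3 alone, so stretches empty in both lists no longer lined up, which can lift the observed value above them. Without empty windows the values were 0.004 at 1 Mb (range -0.136 to -0.055) and 0.386 at 5 Mb (range 0.094 to 0.229). Both stayed above their ranges, but peak-free intervals were not cut out of any window correlation. Windows within one pair of libraries are not independent replicates.

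**Figure D3:**
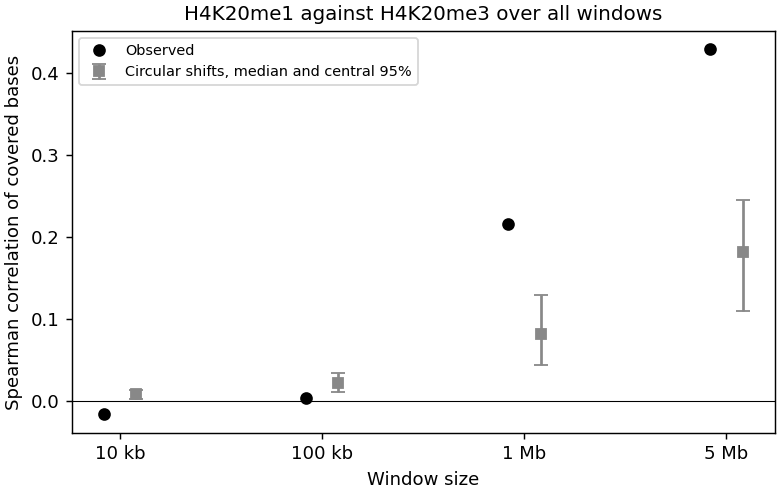
Spearman correlation between bases covered by H4K20me1 and by H4K20me3 over all windows of 10 kb, 100 kb, 1 Mb and 5 Mb (black, observed; grey squares, median of 100 circular shifts with the central 95% range). The observed value lay below the range at 10 kb (-0.017) and 100 kb (0.003) and above it at 1 Mb (0.216) and 5 Mb (0.429).

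Peaks of both marks were more clustered than the same peaks placed independently over the span, peak-free intervals included. Peak callers cut broad marks into pieces, which gives such clusters too, so the comparison does not separate the 2. Joining peaks at most 10 kb apart gave 10726 H4K20me1 domains, against 35439 when the same peaks were placed independently (range 35307 to 35577), and 91.1% of peaks fell in domains of 2 or more. For H4K20me3 there were 5818 domains against 7545 placed (range 7520 to 7580), and 40.4% of peaks fell in domains of 2 or more. H4K20me1 formed 283 domains of 100 kb or longer and H4K20me3 formed 1. The ratio of observed to placed domains was 0.303 for H4K20me1 and 0.771 for H4K20me3, which are not comparable between lists of such unlike peak number. These values depended on the join distance. At 1 kb the ratios were 0.917 and 0.986, below placement in both lists, and 26.5% and 4.05% of peaks fell in domains of 2 or more. At 50 kb the ratios were 0.286 and 0.677, and H4K20me3 formed 81 domains of 100 kb or longer.

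The 10 largest H4K20me1 domains spanned 215.3 to 477.9 kb and lay on chromosomes 5, 6, 7, 8, 10, 12, 16 and 17. The largest, at positions 2070711 to 2548636 of chromosome 7, held 51 peaks that covered 346.4 kb. The next, at 128807456 to 129115875 of chromosome 8, was nearly continuous, with 288.2 kb or 93.4% covered. The third lay at 37788436 to 38152311 of chromosome 6 and had 260.4 kb covered. On chromosome 12, a domain at 124805501 to 125051150 had 217.0 kb covered, and on chromosome 16 one at 89328397 to 89560449 had 215.9 kb. H4K20me3 was absent from the list inside 4 of the 10. With 250 kb added on either side, H4K20me3 covered more than its chromosome's average around 8 of the 10, with a median of 1.99 times that average. The same stretches placed at random on their chromosomes gave 0.374 times (range 0 to 1.26). Kept out of peak-free intervals of 1 Mb or more, they gave 0.558 times (range 0.109 to 1.62).

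The 10 largest H4K20me3 domains were shorter, 37.3 to 125.5 kb, and 6 of them were on chromosome 19 and 3 on chromosome 7. The largest was near the end of the long arm of chromosome 19, at 58665636 to 58791085, where 27 peaks covered 41.9 kb. The second was at 6689859 to 6755751 of chromosome 7, with 36.8 kb covered by 14 peaks. The third was at 36870094 to 36954779 of chromosome 19, with 30.3 kb covered, and the fourth at 56503744 to 56564583 of chromosome 7, with 28.4 kb. Chromosome 19 also held the fifth, sixth and seventh, at 44344430 to 44385257 (25.02 kb), 28053971 to 28125873 (23.7 kb) and 38141138 to 38193705 (23.1 kb).

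H4K20me1 was absent inside 7 of the 10 H4K20me3 domains. With 250 kb added on either side, it covered a median of 0.383 times the average of the same chromosome, inside the range of the same stretches placed at random (0.490 times, range 0 to 1.61). The value also lay inside the range with placements kept out of peak-free intervals of 1 Mb or more (0.702 times, range 0.0666 to 1.82). Around the domain at 38141138 of chromosome 19 H4K20me1 covered 1.20%, against 9.83% for the chromosome. Around the domain at 6689859 of chromosome 7, which held 19664 bp of H4K20me1, it covered 5.74 times the chromosome's average.

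In 1 Mb windows the heaviest H4K20me3 sites were again on chromosome 19, which held 9 of the top 20, with 5 on chromosome 7 and 3 on chromosome 10. These 20 of 2564 windows with any peak contained 14.4% of H4K20me3 bases and 0.998% of H4K20me1 bases. The H4K20me1 share was slightly above the part that 20 windows make up of 2564, so H4K20me1 was not depleted in them together. Singly they ranged from 0 kb of H4K20me1 (62 to 63 and 63 to 64 Mb of chromosome 7) to 359.5 kb (6 to 7 Mb of chromosome 7). The window from 37 to 38 Mb of chromosome 19 had 128.1 kb under H4K20me3 and 1.78 kb under H4K20me1, where the medians of the 2564 windows were 1.19 and 18.0 kb. The window from 58 to 59 Mb had 122.9 and 61.0 kb. On chromosome 10 the window from 44 to 45 Mb had 78.3 and 3.55 kb. Joined at up to 200 kb, the peaks of 36671918 to 38591677 on chromosome 19 formed a stretch of 1.92 Mb with 166 peaks, which held 3.14% of all H4K20me3 bases and was covered to 1.05% by H4K20me1. On chromosome 7, the stretches at 61866655 to 62674501 and 63154804 to 64416302 held 71.3 and 71.6 kb of H4K20me3 and no H4K20me1 peak. Others held more H4K20me1. It covered 4.595% of the stretch with the second most H4K20me3, at 57494664 to 58808398 of chromosome 19, and 4.01% of that at 55718858 to 56950320 of chromosome 7. Both were near the 4.16% of the whole span. Against their own chromosomes, the first lay well below the 9.83% of chromosome 19 and the second near the 4.43% of chromosome 7.

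**Figure D4:**
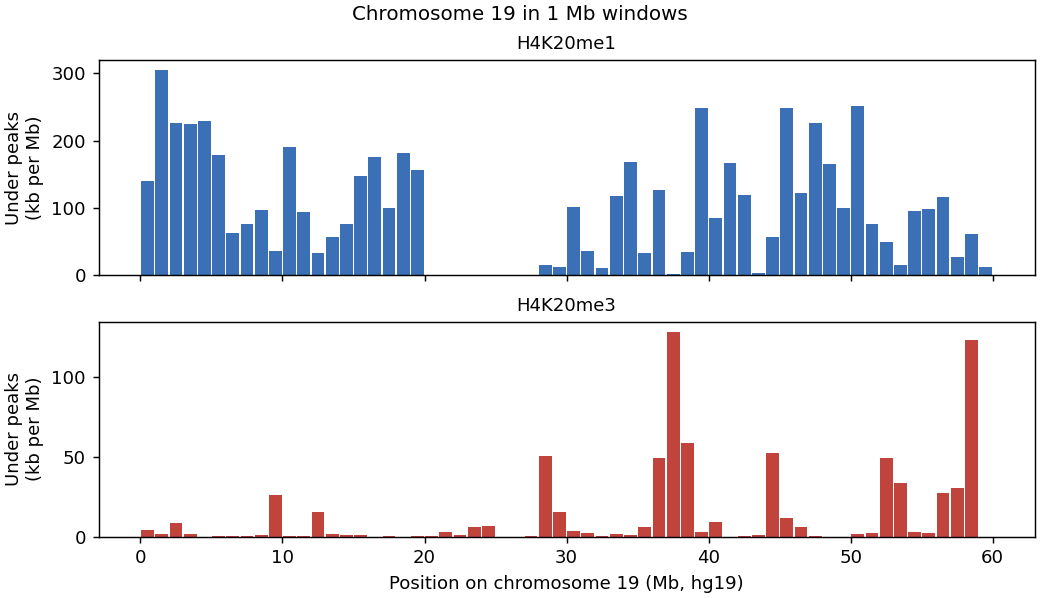
Kilobases under peaks in each 1 Mb window of chromosome 19 (hg19) for H4K20me1 (upper panel) and H4K20me3 (lower panel), 1 library each, on separate linear axes. H4K20me3 was highest at 37 to 38 Mb (128.1 kb) and 58 to 59 Mb (122.9 kb), where H4K20me1 covered 1.78 and 61.0 kb.

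Of the 10 H4K20me1 windows with the most covered bases, 1 was also among the top 20 for H4K20me3, the window from 6 to 7 Mb of chromosome 7. H4K20me3 covered 1.42 to 40.3 kb in the 10 windows, in each above the median of 1.19 kb over the 2564 windows with a peak. By H4K20me3 they ranked from 12 to 1192, so the windows richest in H4K20me1 were not poor in H4K20me3. By H4K20me1 the first was 2 to 3 Mb of chromosome 7, with 578.9 kb. The next was 1 to 2 Mb of the same chromosome, with 524.3 kb. The window from 80 to 81 Mb of chromosome 17 had 441.2 kb and that from 89 to 90 Mb of chromosome 16 had 422.6 kb. Several of these lie close to the end of a chromosome. Over the outermost 5 Mb at 41 chromosome ends, H4K20me1 was denser than on the whole chromosome at 29 ends, with a median ratio of 2.02. H4K20me3 was denser at 26 of the 41, with a median ratio of 1.43. The H4K20me1 ratio was the larger one at 23 of the 41 ends, so no separation of the marks by chromosome ends was seen.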

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

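The H4K20me3 list held 9 peaks outside chromosomes 1 to 22 and X, above the 3 that a count of 0 allows, and these entered no comparison. The H4K20me1 list held 3.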

How the results depend on the processing

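Of the 27 alternatives, 12 left a value inside its interval, range or a factor of 1.5. The restriction to peaks wider than the median, the intervals cut out, the local moves, the removal of peaks beside peak-free intervals, all windows, the 5 Mb windows and the placements kept out of peak-free intervals were chosen after seeing the data. The overlap of H4K20me3 with H4K20me1 stayed below placement in all 7 alternatives run on it, with ratios from 0.290 to 0.450 around 0.412. It was 0.290 with peaks of one mark joined within 10 kb and 0.336 with peak-free intervals of 1 Mb or more cut out. The share of touching peaks (2.29%) was 1.52% when 50% of the peak had to be covered and 7.04% when an H4K20me1 peak within 5 kb counted, both by the construction of the rule. The correlation in 100 kb windows (-0.603) was -0.634 at 10 kb. It turned to 0.004 at 1 Mb, 0.003 with all 100 kb windows, 0.386 at 5 Mb and 0.267 at 5 Mb against the chromosome mean, so its sign was set by window size and by leaving out empty windows. The chromosome 19 share of H4K20me3 (10.1% of bases) was 8.04% by number of peaks and 10.9% among peaks wider than the median. The share of H4K20me3 peaks 1 Mb or more from H4K20me1 was 0.578 of that placed, 0.809 with placements kept out of peak-free intervals of 3 Mb or more, and 1.38 with those of 1 Mb or more kept out, so its direction turned. H4K20me1 domains numbered 38194 with a join distance of 1 kb and 5259 with 50 kb, against 10726. Alternatives with a stricter peak score, gene annotation or base composition were not run, since the lists hold no score and the gene table available was of another build. No paired analysis was possible because each mark had 1 library. Unknown read depth limits all counts of peaks.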

Other observations

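H4K20me3 was more often near long peak-free stretches than H4K20me1 was. The 53 intervals of 3 Mb or more without a peak of either mark, among which any assembly gap of that length counts, had 493 H4K20me3 peaks within 1 Mb, or 6.29% of the list (95% interval 5.76 to 6.85%), against 2.37% of H4K20me1 peaks (2.23 to 2.51%). H4K20me3 formed 60.4% of the 106 edges of these intervals (50.4 to 69.8%). Its 14.9% of all peaks is no baseline for this, because H4K20me1 peaks lay closer together (median gap 2475 against 84967 bp). A less clustered mark borders gaps more often by its spacing alone. No random placement was set beside the shares at edges or within 1 Mb. The 95% interval of the 60.4% overlapped that at the edges of the 302 peak-free intervals of 1 to 2 Mb, 56.0% (51.9 to 60.0%). No difference of the longest ones was thus detected.

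In the paragraphs that follow, the local moves, the removal of peaks beside peak-free intervals, the 5 Mb windows, the test of an even gain of chromosome 19, the count of peaks expected in the chromosome 6 interval and the test of alternative haplotype sequences were chosen after the lists had been examined. The first pattern is the scarcity of overlap. If the marks merely lay in different megabase-scale regions, H4K20me3 peaks moved by 20 to 500 kb would meet H4K20me1 as seldom as the real peaks. They met it more often, and the observed overlap was 0.351 of the local placements (0.320 to 0.393 over their central 95% range), which argues against that explanation as the whole cause. At the same time, the correlation in 5 Mb windows lay above the shifts. Stretches empty in both lists can give this, and they were not cut out there. Differences in mappability or in calling between the lists stay open, because no input or read-level data were analysed here.

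The second pattern is the excess of H4K20me3 on chromosome 19. Its share of H4K20me3 was 2.14 times its share of H4K20me1. Peaks beside long peak-free intervals were not the source, as the ratio was 2.05 without them. Extra copies that multiplied H4K20me3 evenly would have left 21.5% of the 1 Mb windows with a peak below the median of such windows, and 43.1% of 58 were below it (95% interval 30.2 to 56.8%), but over all windows of the span the values were 30.01% and 40.0% of 60 (27.6 to 53.5%). The test multiplied H4K20me3 alone, by 4.87 in windows with a peak. Extra copies would be present in both libraries of the line, so it does not address the ratio of the shares. Extra copies of the chromosome or its parts therefore stay open, as no copy number data were analysed here. The part of its KRAB zinc finger gene clusters was not tested, as gene positions on hg19 were not available.

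The third pattern is an interval of 5.18 Mb on chromosome 6, from 28366025 to 33541816, with no peak of either mark, on the arm that carries the major histocompatibility complex, for which hg19 has several alternative haplotype sequences. The 5 Mb on either side held 39 and 254 H4K20me1 peaks, and at their mean density 151.7 would be expected inside. From the sparser side alone 40.4 would be expected. Both values lay above the bound of 10 that was set, which argues against a sparse region as the reason. The bound did not single this interval out, since 85 of the 112 peak-free intervals of 2 Mb or more passed it. Chance spacing of peaks that lie in clusters therefore stays open. Reads dropped because the alignment index held alternative haplotype sequences might also give such a gap, and the interval had rank 4 among the 112 by the peaks expected from both sides and rank 11 by those expected from the sparser side. On chromosome 17, which also has such a sequence in hg19, the intervals at 43384482 to 44180132 and 44208080 to 45000590 nearly adjoined (ranks 10 and 11 of that chromosome by length), which would go with this explanation if the sequence lies there, but its position was not in the sources used here and the explanations cannot be told apart.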
